A study of Mus musculus with 2 samples.

How the data were processed

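RNA sequencing of CMT167R mouse cells gave 2 libraries, 1 untreated (CON) and 1 from cells treated with 50 nM of a compound the labels call PKCi for 24 h. Samples were grouped by the treatment named in the labels. Per the labels' descriptions, RNA was column-purified, stranded poly(A) mRNA libraries were made with a TruSeq kit, and a NovaSeq instrument gave paired-end reads. A second protocol in the labels speaks of frozen retinas, Trizol and a TruSeq kit that does not mark strand, which differs from the cell culture described elsewhere in the same labels; retina markers are given with the other observations. Per the submitters' processing notes, HISAT2 2.0.5 and the mouse builds GRCm38 and mm10 were used. The counting program, its strand setting, the annotation release and any filter are not given in the sources used here.

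The authors deposited a single table with 54532 genes and whole-number counts per gene, 1 column per library, with gene symbols, positions, lengths and biotypes. The name of the deposited table speaks of FPKM, but its values are whole numbers, all integers from 1 to 20 occur in each column, and the columns sum to 16090186 (CON) and 16071153 (PKCi), so they were used as raw counts. The plan, written for FPKM before the data were examined, also covered raw counts, which it turned into counts scaled to the library total (CPM) for a description without a test; its 1 FPKM settings became 1 CPM. The gene lengths are as listed per the file headers. Per-sample columns that could not be assigned numbered 0. Of the deposited gene identifiers, 54495 were in GENCODE M21, and 98.3% of these had the same chromosome, start and end. In the symbol column, 27 symbols had been turned into dates and were not used by name, and 102 symbols stood at more than 1 gene, of which the one with the highest summed count was used. Reads that near-identical paralogs, pseudogenes, overlapping genes or antisense genes share could be split in ways the table does not show.

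Counts were divided by the library total and multiplied by 1000000. Genes with at least 1 CPM in at least 1 library were used (12273, of which 10943 were protein-coding), and the log2 ratio was log2((PKCi + 1)/(CON + 1)) in CPM. The pseudocount of 1 CPM shrinks the ratio of low genes, so a fold in the text is the plain ratio of CPM. With 1 library per group no test across conditions was possible; genes were counted at a size of at least 2-fold on the log2 scale. Each fold has an exact conditional binomial (Clopper-Pearson) 95% interval from the counts of that gene and the library totals, which compares these libraries and covers counting error only, as reads without molecular identifiers are not independent molecules. A count of 0 was given a floor of 3 counts per library. Before the data were examined, 40 gene lists were written. For the 36 with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and its percentile describes these libraries only. The random lists ignore that genes of a pathway vary together. Lists share members. Markers of other cell types (leukocytes, fibroblasts, endothelium, lung epithelium and retina) were also summed, with and without the marker that had the most counts, a step added after the data were seen.

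The genes named in the text follow a rule written before the data were examined. It took the 10 highest and 10 lowest log2 ratios among protein-coding genes with at least 5 CPM in a library, leaving out predicted (Gm and Rik) symbols, and up to 4 members of each list with the largest absolute log2 ratio. Xiap, all Prkc genes, Cd274, B2m, H2-K1, H2-D1, Calr, Hmgb1, Cxcl10 and Mki67 were named whatever their values. List members under 1.5-fold could be left out, and some genes that the rule names are not reported here.

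The untreated library had 18284 genes with a count and 11700 with at least 1 CPM, and the PKCi library 19071 and 11924. The 10 most abundant genes took 4.83% and 6.22% of counts, mitochondrially encoded genes 2.51% and 2.90%, and protein-coding genes 98.4% and 98.3%. The procedure was tested on simulated libraries of the PKCi against CON comparison made from the mean levels of all 54532 genes. Changes were planted only in genes with a mean of at least 5 CPM. At 3-fold and at 4-fold, 50 of 50 of these were recovered in each direction. Recovery of genes with a mean under 5 CPM was not simulated. Of 11884 unchanged genes 0 passed 2-fold, and 95.5% of counting intervals held the true ratio. Of 200 random lists without a difference, 6% fell outside the middle 95%. These libraries carried counting noise only, so they say nothing about differences between cultures. In the same simulation a trend was planted over 12084 genes, with gene length and with a random value standing in for GC content. Its Spearman's rho of 0.588 and 0.737 was reduced to 0.022 and 0.019. A list of randomly drawn genes planted with a shift kept 1.01 of its 1.01 on the log2 scale. Real GC content, and lists whose members share length or GC content, were not simulated.

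Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5 CPM, no filter and a filter of 5 CPM, TPM, upper-quartile and median-ratio scaling, protein-coding genes only, removal of mitochondrially encoded genes, size rules of 1.5-fold and 4-fold, a rule on the counting interval and unmatched random lists. FPKM computed from the counts and listed lengths, and removal of length and GC trends (20 bins each, GC content from GENCODE M21 transcripts for 99.9% of measured genes), were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.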

Results

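Messenger RNA was sequenced from 2 cultures of CMT167R cells. CMT167 is a mouse lung carcinoma line, and the labels describe the CMT167R cells as resistant to anti-PD1, an antibody treatment that blocks an inhibitory receptor of T cells. The untreated library (CON) and the library from cells given 50 nM of a compound that the labels call PKCi for 24 h made up the whole design, with 1 library in each group. The labels do not say which compound PKCi is. The untreated library held 16090186 gene counts and the PKCi library 16071153, and levels are given as counts scaled to a library total of 1000000 (CPM), where 1 CPM stood for 16.1 counts in each library. A count of 0 allowed a level of up to 0.186 CPM in the untreated library and 0.187 CPM in the PKCi library (3 counts of the total). With 1 library per group no difference below has a replicate check, no p-value is given, and the 95% intervals of folds cover counting error only.

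The comparison addressed how the PKCi compound altered gene expression in the resistant cells, in a study whose title joins XIAP, protein kinase C signalling and resistance to immunotherapy. The PKCi library held lower levels of YAP and TEAD target genes and of DNA replication and mitosis genes. It held higher levels of NF-kB target genes, of genes downstream of ERK and AP-1, of interferon gamma response genes and of lysosome genes. Itga2, an integrin subunit that binds collagen, was 59.0-fold higher in the PKCi library (95% interval 40.7 to 89.1), and Ctgf, a secreted matrix-associated protein, was 59.7-fold lower (95% interval 43.7 to 83.8). Among 12273 genes with at least 1 CPM in at least 1 library, 802 (6.53%) were at least 2-fold higher and 630 (5.13%) at least 2-fold lower in the PKCi library on the log2(CPM + 1) scale. At least 4-fold differences were seen for 119 genes that were higher and 36 that were lower. The median log2 ratio over all 12273 genes was −0.01, with quartiles at −0.41 and 0.39, and Pearson's r of log2(CPM + 1) between the libraries across genes was 0.9503 (genes are not independent replicates).

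**Figure D1:**
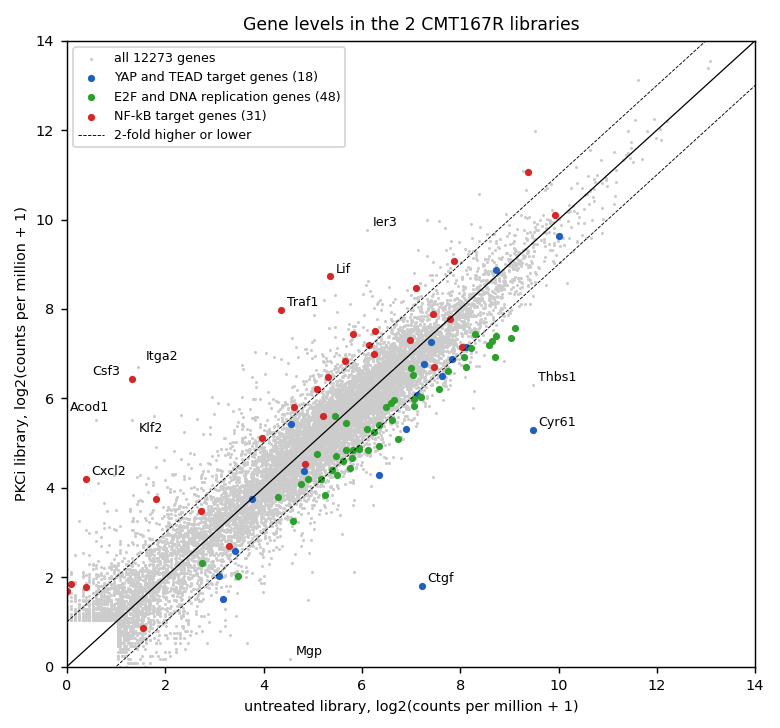
Each point is a gene, placed by its log2(CPM + 1) in the untreated library (horizontal) and in the PKCi library (vertical), with the diagonal marking equal levels and dashed lines 2-fold differences. The 48 measured DNA replication genes (green) lie below the diagonal except for 1, and 25 of the 31 NF-kB target genes (red) lie above it.

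Itga2 had the highest log2 ratio of the protein-coding genes with at least 5 CPM in a library, followed by Csf3, the granulocyte colony-stimulating factor, at 1.49 CPM untreated and 85.7 CPM with PKCi (57.5-fold higher, 95% interval 38.5 to 90.03). Acod1, the enzyme that makes itaconate, was at 0.497 and 44.8 CPM, and the transcription factor Klf2 at 1.49 and 45.1 CPM. The integrin subunit gene Itgb7 was 19.8-fold higher, the neutrophil chemokine Cxcl2 55.9-fold higher (5 against 279 counts, 95% interval 23.7 to 173), and the early response gene Ier3 12.9-fold higher, from 67.7 to 871 CPM. Igfbp5, Traf1 and the tetraspanin Cd53 completed the 10 highest, with log2 ratios of 3.66, 3.61 and 3.47. The 10 lowest were led by Ctgf, which was at 149 CPM untreated and 2.49 CPM with PKCi. Mgp, an inhibitor of calcification, had 360 counts untreated and 2 with PKCi (180-fold lower, 95% interval 49.4 to 1490). Cyr61, a matricellular protein related to Ctgf, was 18.5-fold lower (709 and 38.4 CPM), and Thbs1, thrombospondin 1, was 9.13-fold lower (709 and 77.7 CPM). The others were Clca3a1, the actin-bundling protein gene Fscn1, the collagen gene Col8a1, Wisp1, the RNA-binding protein gene Igf2bp1 and the activin antagonist gene Fst, which were 16.8-, 16.1-, 9.67-, 26.8-, 9.10- and 7.02-fold lower. On the mouse GRCm38 coordinates of the deposited table, Itga2 (ENSMUSG00000015533) spans chromosome 13 from 114833081 to 114932100 on the minus strand, and Ctgf (ENSMUSG00000019997) spans chromosome 10 from 24595442 to 24598683 on the plus strand.

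YAP and TEAD target genes, which respond to the Hippo pathway and to cell tension, were lower as a group in the PKCi library. Of 18 measured members 8 were at least 2-fold lower and 0 at least 2-fold higher, with 16 below a log2 ratio of 0. The median log2 ratio was −0.96 (95% order-statistic interval −1.59 to −0.36), and 0 of 10000 random lists matched on expression had a median as low. Besides Ctgf and Cyr61, Ankrd1, a cardiac and stretch-related ankyrin protein, was 4.32-fold lower (80.4 and 18.6 CPM), and F3, tissue factor, 4.33-fold lower (8.08 and 1.87 CPM). Of the 18 measured genes of the SRF and actin cytoskeleton list, 5 were at least 2-fold lower and 0 higher, with a median of −0.52 (95% interval −1.04 to 0.25) at the 0.1 percentile of its random lists. Smooth muscle actin Acta2 was at 3.67 and 0.249 CPM (59 and 4 counts, 14.7-fold lower, 95% interval 5.46 to 55.9), tropomyosin Tpm1 at 855 and 373 CPM, and Fhl2 at 31.4 and 12.6 CPM. The myosin light chain gene Myl9 had 32 counts untreated and 0 with PKCi, at least 10.7-fold lower against a floor of 3 counts, where the 95% counting interval, which also covers the error of the 32 counts, begins at 8.17-fold lower. With no filter on low values the SRF list's median was −0.17, at the 8.53 percentile, inside the range of its random lists.

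**Figure D2:**
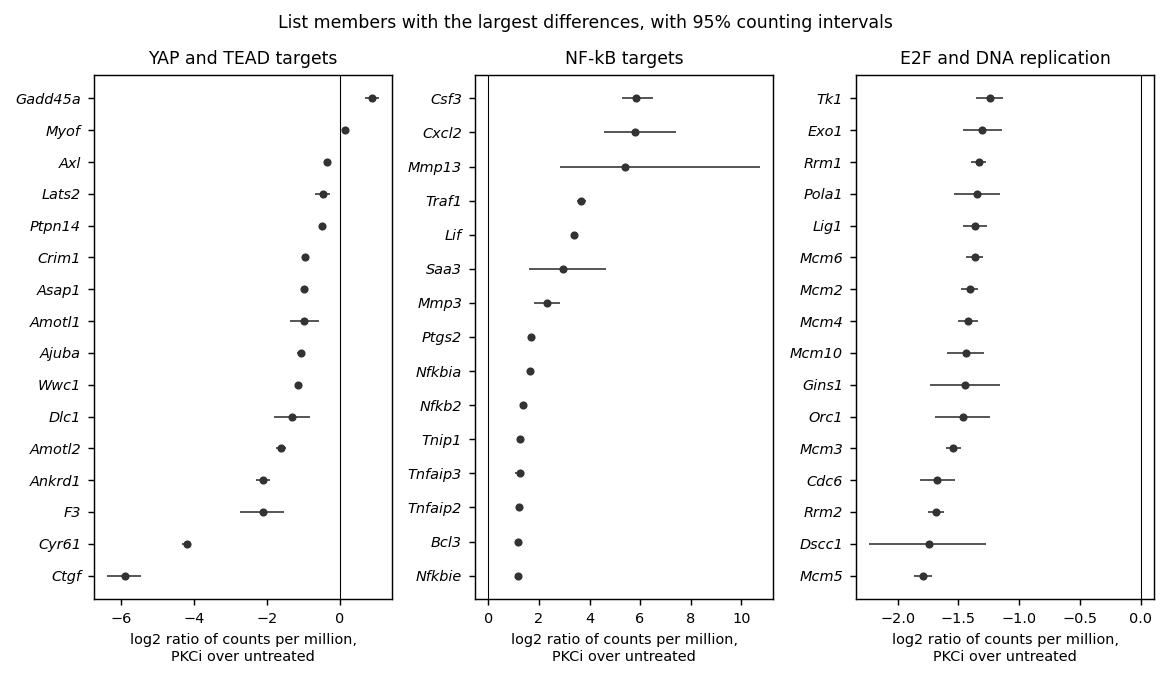
Points give log2 ratios of CPM (PKCi over untreated, horizontal) for the members with the largest differences in 3 gene lists, leaving out members with 0 counts in a library, and bars are 95% counting intervals. Ctgf and Cyr61 lie farthest below 0 among the YAP and TEAD targets, Csf3 and Cxcl2 lie highest among the NF-kB targets, and Mcm5 is the lowest of the DNA replication genes.

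Genes of cell proliferation were lower in the PKCi library, across DNA replication and mitosis alike. Of 48 measured E2F and DNA replication genes, 29 were at least 2-fold lower and 47 had a log2 ratio below 0, with a median of −1.08 (95% interval −1.21 to −0.95) that 0 of 10000 random lists reached. Mcm5 and Mcm3, subunits of the replicative helicase, were 3.46-fold and 2.91-fold lower. Rrm2, a subunit of ribonucleotide reductase, was at 522 and 162 CPM, and the replication licensing gene Cdc6 at 105 and 33.0 CPM. All 56 measured mitosis and G2/M genes had log2 ratios below 0, 16 of them at least 2-fold lower, with a median of −0.90 that 0 of 10000 random lists reached. Cyclin A2 (Ccna2) was 3.05-fold lower, the anaphase activator Cdc20 2.90-fold lower, Cdc25c 2.62-fold lower and Pbk 2.56-fold lower. The proliferation marker Mki67 was at 467 CPM untreated and 351 CPM with PKCi (1.33-fold lower, 95% interval 1.29 to 1.38). Replication-dependent histone genes went the other way: 4 of 10 measured were at least 2-fold higher and 0 lower, with a median of 0.93 at the 99.88 percentile. With TPM scaling the histone list was at the 97.27 percentile, inside the range, and over the settings tried its median ranged from 0.16 to 1.86. Among them Hist1h2bc was at 6.53 and 39.9 CPM and the linker histone gene Hist1h1c at 35.5 and 126 CPM. Hist1h1d was 4.42-fold higher, and Hist1h2bn had 1 count untreated and 28 with PKCi (28.0-fold, 95% interval 4.63 to 1150). Messages of this class mostly lack a poly(A) tail and are poorly sampled by poly(A)-selected libraries, and histone paralogs can share reads.

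NF-kB target genes were higher in the PKCi library, among them cytokines and regulators of the pathway itself. Of 31 measured, 19 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.15 (95% interval 0.44 to 1.39) that 0 of 10000 random lists reached. Of the 31, 25 were above 0 and 6 below. Those below included the cytokine genes Csf1 (260 and 142 CPM) and Cxcl5 (176 and 103 CPM), chosen after their values were seen. Besides Csf3 and Cxcl2, the cytokine gene Lif was 10.6-fold higher (40.0 and 423 CPM), and Traf1, an adaptor of TNF receptors, 12.8-fold higher (19.6 and 251 CPM). Other lists also held 13 of these 31 genes. In the chemokine and cytokine list, 9 of 22 measured genes were at least 2-fold higher and 1 lower, with 13 above 0 and 9 below. The median was 0.40 (95% interval −0.69 to 1.70) at the 98.5 percentile, and 10 of the 22 stood in another list. Cxcl16, a transmembrane chemokine, was 5.98-fold higher (19.6 and 117 CPM). Cxcl10, a chemokine that attracts T cells, had 18 counts untreated and 4 with PKCi (4.49-fold lower, 95% interval 1.48 to 18.3). With no filter on low values the chemokine median was 0.15, at the 88.8 percentile. Genes downstream of ERK and AP-1 were higher as a group, 16 of 45 at least 2-fold higher and 2 lower, with a median of 0.85 that 0 of 10000 random lists reached. Of the 45, 37 were above 0 and 8 below. The 2 at least 2-fold lower, named after their values were seen, were Spry1 (114 and 33.0 CPM) and Epha4 (27.4 and 10.8 CPM). Junb, an AP-1 subunit, was at 140 and 636 CPM, Klf6 at 93.3 and 360 CPM, and the matrix metalloproteinase gene Mmp3 at 2.49 and 12.4 CPM. Summed counts of 22 leukocyte markers, of which 16 were at 0 in both libraries, were lower in the PKCi library (13.98 and 8.34 CPM, ratio 0.596, 95% interval 0.478 to 0.742). Without Lyz2 the ratio was 0.914 (95% interval 0.672 to 1.24).

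The MHC class I and interferon gamma response lists had medians above their random lists, with class I members on both sides of 0. Of 17 measured genes of MHC class I presentation, 4 were at least 2-fold higher and 0 lower, 13 were above 0 and 4 below, and the median was 0.39 (95% interval 0.04 to 0.83) at the 99.3 percentile. Those below 0, named after their values were seen, were Calr, Canx, Pdia3 and Psmb10, of which Calr, Canx and Pdia3 encode chaperones of the endoplasmic reticulum. The rest of the 23 listed class I genes, Tap1, Psmb8 and Psmb9 among them, were under 1 CPM in both libraries. Tapasin (Tapbp), which loads peptides onto class I molecules, was 3.25-fold higher and its relative Tapbpl 3.21-fold higher. H2-T23, a non-classical class I gene, was 4.68-fold higher (10.6 and 49.8 CPM), and Nlrc5, a transactivator of class I genes, had 7 and 43 counts. Beta-2 microglobulin (B2m) was at 185 and 328 CPM, H2-D1 at 354 and 501 CPM, and H2-K1 at 209 and 221 CPM (1.06-fold, 95% interval 1.01 to 1.11). Class I genes are near-identical in part, so reads could be split among H2-K1, H2-D1 and H2-T23. Of 24 measured interferon gamma response genes, 8 were at least 2-fold higher and 0 lower, with a median of 0.77 at the 99.99 percentile. Gbp2, a guanylate-binding protein, was 9.82-fold higher (10.8 and 106 CPM), Upp1 4.42-fold, Gbp9 2.86-fold and the receptor subunit gene Ifngr2 2.44-fold higher. The type I interferon list was within the range of its random lists, at the 94.5 percentile with a median of 0.27. It had 4 of 26 genes at least 2-fold higher, including Parp14 (5.72-fold) and Trim30a (2.78-fold), and 2 at least 2-fold lower, Ifit2 (4.64-fold) and Bst2 (2.27-fold). Of 14 measured genes of nucleic acid sensing, 3 were at least 2-fold higher, with a median of 0.40 (95% interval −0.28 to 1.03) at the 97.8 percentile. The kinase gene Ikbke was at 9.51 and 38.1 CPM and the DNA sensor gene Aim2 at 1.62 and 6.91 CPM, Tlr9 had 3 and 23 counts (7.68-fold, 95% interval 2.32 to 39.9), and Mb21d1, which encodes the sensor cGAS, was 2.16-fold lower. With TPM scaling this list was at the 97.0 percentile, inside the range. Of the MHC class II list 2 genes were measured, H2-DMa at 1.24 and 2.99 CPM and H2-DMb1 at 3.11 and 3.55 CPM.

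Immune checkpoint ligand genes had a median of 0.42 (95% interval −0.03 to 0.79) over 17 measured members, at the 98.6 percentile, with 1 at least 2-fold higher (H2-T23) and 1 at least 2-fold lower. The latter was Lgals9, galectin 9, at 14.6 and 4.73 CPM. This list is not limited to inhibitory ligands: it also holds the death receptor gene Fas, the costimulatory ligand gene Tnfsf9 and the activating ligand genes Raet1e and Ulbp1. Cd274, which encodes PD-L1, was at 1.74 and 2.68 CPM (28 and 43 counts), a difference not detectable at this depth (1.54-fold, 95% interval 0.934 to 2.57). Pvr, a ligand of CD226 and TIGIT, was 1.98-fold higher, and Vsir had 4 and 23 counts (5.76-fold, 95% interval 1.97 to 22.9). Of 19 measured damage-associated and immunogenic cell death genes, 2 were at least 2-fold higher and 1 lower, with a median of −0.26 at the 7.26 percentile, inside the range. Hmgb1, a nuclear protein released by dying cells, was at 134 and 67.2 CPM, Hmgb2 was 2.43-fold lower and calreticulin (Calr) 1.53-fold lower (1880 and 1225 CPM). The ATP-gated channel gene P2rx4 was 2.33-fold higher and Vamp1 2.45-fold higher.

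Xiap, which encodes the caspase inhibitor in the study's title, was at 41.0 CPM untreated and 56.7 CPM with PKCi (660 and 911 counts, 1.38-fold higher, 95% interval 1.25 to 1.53). The gene (ENSMUSG00000025860) lies on chromosome X from 42059679 to 42109656 on the plus strand. Inhibitor of apoptosis genes and their partners had no group difference outside their random lists (22 measured, 1 at least 2-fold higher, 3 lower, median 0.06, percentile 68.0). Birc5, survivin, was 2.05-fold lower, the XIAP antagonist gene Htra2 2.05-fold lower, Siva1 2.15-fold lower, and Xaf1, which binds XIAP, had 10 and 40 counts. Among 15 measured BCL2 family genes 3 were at least 2-fold higher and 1 lower, with a median of 0.00 at the 54.8 percentile. The 3 were the pro-apoptotic BH3-only genes Bcl2l11 (3.38-fold), Bmf (3.41-fold) and Bbc3 (3.22-fold), and the survival gene Bcl2 itself was 2.82-fold lower (76.4 and 27.1 CPM). Of 13 measured pyroptosis and necroptosis genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.35 at the 93.01 percentile, inside the range. It was outside the range with TPM scaling (98.4 percentile) and with length and GC trends removed (99.1 percentile), and with a filter of 5 CPM its median was −0.07. Nlrp3, an inflammasome sensor, had 2 and 75 counts (37.5-fold, 95% interval 10.04 to 316), Casp1 6 and 32 counts, and Gsdmd was at 5.84 and 14.4 CPM.

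Protein kinase C genes differed in direction. Prkci, which encodes the atypical isoform iota, was 2.20-fold lower in the PKCi library (145 and 66.0 CPM, 95% interval 2.04 to 2.36), and Prkcz, the other atypical isoform, was 2.27-fold higher (11.9 and 26.9 CPM, 95% interval 1.91 to 2.71). Prkcd was at 31.4 and 53.9 CPM, Prkca at 58.2 and 66.3 CPM and Prkce at 18.0 and 23.8 CPM. Prkch had 4 and 18 counts, and Prkcb and Prkcq had 0 in both libraries, at or under 0.187 CPM. The list of protein kinase C and related kinases also holds lipid kinases (diacylglycerol kinases) and non-kinase genes, such as phospholipase C genes, Marcks and Rack1. Over its 29 measured genes the median was 0.41 (95% interval −0.08 to 0.58), at the 99.93 percentile, and the mean 0.15. Of these, 18 were above 0 and 11 below, with 1 at least 2-fold higher and 2 lower. The phospholipase C gene Plce1, a member of this list, was 6.12-fold lower (29.3 and 4.79 CPM), and the protein kinase D gene Prkd2 was 1.75-fold higher.

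Of 14 measured heat shock response genes 4 were at least 2-fold lower and 0 higher, 11 were below 0 and 3 above, and the median was −0.74 (95% interval −1.42 to 0.06) at the 0.02 percentile. The mitochondrial chaperonin genes Hspd1 and Hspe1 were 2.99-fold and 2.69-fold lower, the co-chaperone gene Fkbp4 2.10-fold lower, and the small heat shock protein gene Cryab 6.21-fold lower (87 and 14 counts). Of 35 lysosome and autophagy genes 5 were at least 2-fold higher and 0 lower, with a median of 0.48 that 0 of 10000 random lists reached. The autophagy genes Wipi1, Map1lc3b and Sqstm1 were 3.68-, 2.82- and 2.56-fold higher, and the protease gene Ctsl 2.52-fold higher (646 and 1627 CPM). The unfolded protein and integrated stress response list held 7 of 39 genes at least 2-fold higher and 4 lower (median −0.16, percentile 17.4). Slc7a11, the cystine transporter, was 5.05-fold higher, Nupr1 2.86-fold higher and Ddit4 2.54-fold higher, while Creld2, a chaperone of the endoplasmic reticulum, was 2.56-fold lower. NRF2 targets had 4 of 25 genes at least 2-fold higher and 0 lower, with a median of −0.03 at the 56.4 percentile and a mean of 0.28. Besides Slc7a11 they were Hmox1, heme oxygenase 1 (2.58-fold), Mgst1 (2.88-fold) and Abcc4 (2.76-fold). Targets of p53 had 4 of 30 genes at least 2-fold higher and 3 lower, with a median of −0.18 at the 10.9 percentile and a mean of 0.02. Trp53inp1 was 4.43-fold and Btg2 3.69-fold higher, and Psrc1 was 2.38-fold lower.

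In the glycolysis and hypoxia list 7 of 36 genes were at least 2-fold higher and 1 lower, with 20 above 0 and 16 below and a median of 0.25 (95% interval −0.11 to 0.61) at the 99.8 percentile. Ndrg1 was 6.30-fold higher (160 and 1008 CPM), the angiogenic factor Vegfa 4.58-fold higher, Ankrd37 6.79-fold and Mxi1 2.62-fold higher. With no filter on low values the list's median was 0.09, at the 94.3 percentile. Nuclear-encoded oxidative phosphorylation genes had a median of −0.38 at the 0.06 percentile, with 40 of 49 below 0, 1 at least 2-fold lower and 0 higher. The ATP synthase gene Atp5g1 was 2.14-fold lower, Ndufa9 1.94-fold, Ndufa5 1.80-fold and Cyc1 1.62-fold lower. The 12 measured messages encoded by the mitochondrial genome had a median of 0.10 at the 83.1 percentile, with mt-Co1 at 1.28-fold and mt-Nd5 at 1.30-fold of the untreated level and mt-Atp6 1.58-fold lower. Fatty acid synthesis genes had a median of −0.38 (95% interval −0.81 to 0.18) at the 2.26 percentile, with 1 of 17 at least 2-fold higher and 1 lower. Acacb was 3.37-fold lower, Elovl6 1.95-fold and Acaca 1.93-fold lower, while Acsl4, which activates arachidonic acid, was 2.87-fold higher. With TPM scaling this list was at the 4.37 percentile. Cholesterol biosynthesis genes had a median of −0.29 at the 3.47 percentile, inside the range, with Acat2 the 1 gene of 25 at least 2-fold lower (2.05-fold).

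Lists of cell identity stayed mostly within the range of their random lists. Epithelial genes (21 measured, 0 at least 2-fold higher, 1 lower) had a median of 0.17 at the 82.0 percentile, with Cldn1, a tight junction gene, at 24 counts and 1 count (24.0-fold lower, 95% interval 3.91 to 986). Mesenchymal transition genes (22 measured, 2 higher, 4 lower) had a median of 0.06 at the 73.6 percentile and a mean of −0.09, with Pdgfrb 3.62-fold, the proteoglycan gene Bgn 3.73-fold and the collagen crosslinking enzyme gene Lox 3.30-fold lower. TGF-beta targets (21 measured, 4 higher, 4 lower) had a median of 0.30 (95% interval −0.48 to 0.90) at the 99.03 percentile but a mean of −0.10, with Ldlrad4 3.60-fold and Id3 3.16-fold higher and Ctgf and Thbs1 among those lower. The TGF-beta list was inside the range with length and GC trends removed (97.2 percentile) and with unmatched random lists (97.3 percentile). Wnt targets (13 measured, 0 higher, 1 lower) had a median of −0.23 at the 13.6 percentile, with the Wnt inhibitor gene Notum 2.90-fold lower, Ccnd1 1.78-fold lower and Sox9 1.91-fold higher. Cytosolic ribosomal protein genes (62 measured) had a median of 0.00 at the 86.5 percentile and 1 gene at least 2-fold higher, Rps27a (2.61-fold), a family whose reads can be shared with processed pseudogenes. Housekeeping genes (18 measured, 0 past 2-fold) had a median of −0.16 at the 24.8 percentile, with B2m 1.78-fold higher, Gapdh 1.61-fold lower and Gusb 1.66-fold lower. Summed fibroblast markers were at 89.1 and 85.6 CPM (ratio 0.960, 95% interval 0.891 to 1.03), most of them from Gsn, and their 5 measured genes had a median of 0.85 (range of the 5 −0.88 to 0.95) at the 98.1 percentile and a mean of 0.35, which left the outer range with no filter on low values (0.13, percentile 76.7). Summed endothelial markers were at 3.42 and 3.48 CPM (ratio 1.02, 95% interval 0.690 to 1.51), most of them from Egfl7, and without it at 0.808 and 1.62 CPM (13 and 26 counts, ratio 2.002, 95% interval 0.993 to 4.24). Summed lung epithelium markers were at 409 and 301.0 CPM (ratio 0.737, 95% interval 0.710 to 0.765), most of them from Aqp5 at 291 and 153 CPM. Without Aqp5 the sum was higher in the PKCi library (118 and 148 CPM, ratio 1.26, 95% interval 1.18 to 1.33), with Abca3 at 48.4 and 87.9 CPM and Foxa1 at 4.23 and 17.4 CPM. The 5 measured lung epithelium genes had a median of −0.36 at the 13.4 percentile and a mean of 0.03.

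**Figure D3:**
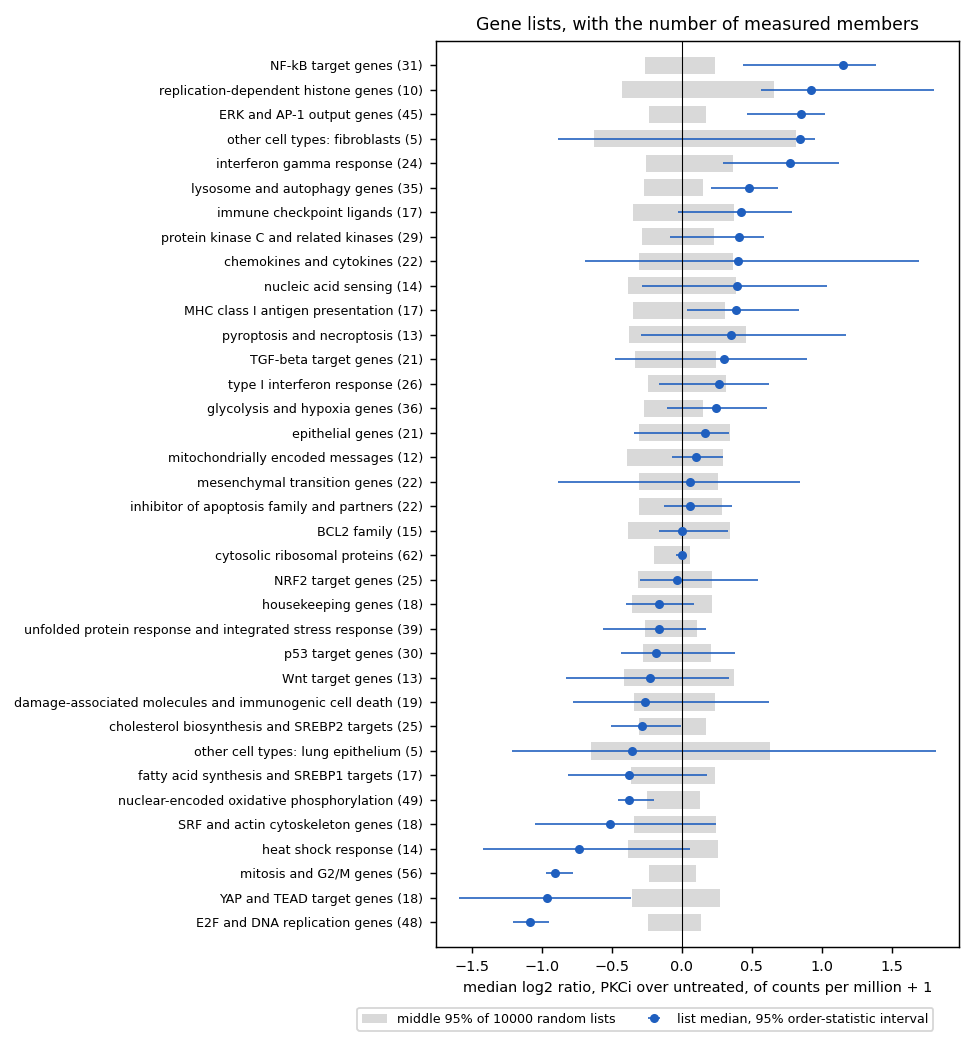
Points are the median log2 ratio (PKCi over untreated, horizontal, from CPM + 1) of each gene list with at least 5 measured members, bars are 95% order-statistic intervals, and grey blocks hold the middle 95% of 10000 random lists matched on expression. Of 36 lists, 13 lie above their grey block and 7 below it, where 1.8 would lie outside by chance if list members were unrelated, which co-regulated genes and shared members are not.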

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

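FPKM computed from the counts and the removal of length and GC trends were chosen after seeing the data. Over 12 alternative settings, 12 of the 20 lists outside the range of their random lists stayed outside in every one, 7 higher and 5 lower, and none of the 20 lists and no named gene past 2-fold changed direction. The 12 are the MHC class I, interferon gamma, NF-kB, checkpoint ligand, protein kinase C, ERK and AP-1 and lysosome lists, and the YAP and TEAD, heat shock, DNA replication, mitosis and nuclear oxidative phosphorylation lists. The NF-kB median ranged from 0.94 to 1.19, that of YAP and TEAD targets from −1.01 to −0.80, and that of DNA replication genes from −1.10 to −0.98. Without a filter 4 lists moved inside the range (chemokines, SRF, glycolysis and hypoxia, fibroblasts), with TPM 3 (nucleic acid sensing, fatty acid synthesis, histones at the 97.3 percentile), and with trends removed 2 (TGF-beta at the 97.2 percentile, fibroblasts at 95.9). Fatty acid synthesis was at the 8.41 percentile with FPKM, TGF-beta at 97.3 with unmatched random lists, and fibroblasts at 97.4 with a 0.1 CPM pseudocount and 96.6 with protein-coding genes only. Lists that moved outside were pyroptosis (98.4 percentile with TPM, 99.1 with trends removed), mitochondrially encoded messages (97.96 with trends removed) and type I interferon (97.6 with unmatched lists).

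Genes at least 2-fold higher and lower numbered 1398 and 985 with TPM, 2058 and 2048 with a 1.5-fold rule, and 119 and 36 with a 4-fold rule; the cause of the TPM counts was not tested. Calls were higher rather than lower in 56.0% with CPM, and in 53.9% to 61.3% with the other scalings and filters. The median log2 ratio of all genes was 0.027 without a filter, −0.039 with a 5 CPM filter, 0.00839 with TPM, 0.020 with upper-quartile and 0.033 with median-ratio scaling. The histone list was at 1.86 with a 0.1 CPM pseudocount and 0.16 without a filter, and the fibroblast list at 1.15 with 0.1 CPM and 1.04 with 0.5 CPM. Ribosomal protein genes were at 0.031 with upper-quartile, 0.046 with median-ratio scaling and 0.023 with trends removed, and mitochondrially encoded messages at 0.29 with trends removed. The cause of these moves was not tested. The histone list had too few measured genes for a value with a 5 CPM filter, as had the fibroblast list with that filter, TPM or FPKM. A rule on the counting interval left the counts as they were, since a gap of 2-fold in CPM + 1 always clears it. Depth limits genes near 0.187 CPM, the level that 3 counts give.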

Other observations

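Gene groups that were not among the planned lists also differed, and 5 were added after the data were seen. These 5 lists were not run through the alternative settings, removal of length and GC trends included. The list of ribosome biogenesis and MYC target genes, which also holds enzymes of nucleotide and polyamine synthesis, had 21 of 60 measured members at least 2-fold lower in the PKCi library and 58 below a log2 ratio of 0. Their median was −0.90 (95% interval −0.998 to −0.813). The pseudouridine synthase gene Dkc1 was at 119 and 37.9 CPM, nucleolin (Ncl) at 1886 and 832 CPM, and Lyar at 88.1 and 30.2 CPM, genes chosen after their values were seen. The 1 member at least 2-fold higher was Odc1, ornithine decarboxylase, at 736 and 4028 CPM. Myc itself was at 101 and 128 CPM. Mitochondrial ribosomal proteins had 70 of 77 measured genes below 0 and a median of −0.44, which 0 of 10000 random lists reached, while cytosolic ribosomal proteins had a median of 0.00. All 8 genes of the CCT chaperonin, which folds actin and tubulin, were below 0, with a median of −0.68 at the 0.14 percentile; the value of Cct2 had been seen before this list was written. Integrin subunits had 2 of 15 at least 2-fold higher, the Itga2 and Itgb7 that led to the list, and a median of 0.20 at the 89.3 percentile, inside the range. That list first also held 2 integrin-binding proteins, taken out as no subunits, with which it was at the 89.4 percentile.

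Retina markers were looked at because a protocol in the labels speaks of retinas. Of 23, 21 were under 1 CPM in both libraries, 16 were at 0 in both, and their sum was 10.9 CPM untreated and 9.64 CPM with PKCi (ratio 0.887, 95% interval 0.710 to 1.11). The 2 measured were Gnat2, at 3.29 and 1.49 CPM, and Rom1, at 6.40 and 6.53 CPM.

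The tests of library scaling, of leukocyte RNA and of FOXO targets in the next paragraphs were chosen or edited after the values they use had been seen, and the removal of length and GC trends was an added alternative.

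The YAP and TEAD target list was lower in the PKCi library. A bias of gene length or GC content is argued against, since the median was −1.01 (95% interval −1.59 to −0.44) after both trends were removed. The list stayed lower in 5 other settings, with a value nearest 0 of −0.80. These were TPM, upper-quartile and median-ratio scaling, FPKM and removal of mitochondrially encoded genes. A change of scaling factor moves all log2 ratios by nearly the same amount, and the median of all genes moved little. The check therefore had little room to come out otherwise, and no conclusion on scaling is drawn from it. FPKM divides by the same library totals as CPM, so it changes ratios only through the pseudocount and filter. None of the scalings measures total RNA per cell, so a change in total RNA content was not tested. Also open is the treatment against any other difference between the cultures. Cell density also sets YAP activity, and with 1 library per group these cannot be separated.

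The NF-kB target list was higher in the PKCi library. Length or GC bias is argued against by a median of 1.08 (95% interval 0.44 to 1.44) after removal of both trends. RNA from leukocytes, which express many of these cytokines, is argued against by Ptprc, Tyrobp, Laptm5 and Cd52, abundant in leukocytes, at 0 counts in both libraries. Summed leukocyte markers were at 0.596 of the untreated level (95% interval 0.478 to 0.742), a difference that rests on Lyz2, since without it the ratio was 0.914 (95% interval 0.672 to 1.24). A difference between cultures other than the treatment stays open.

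The DNA replication list was lower in the PKCi library. Length or GC bias is argued against by a median of −1.03 (95% interval −1.23 to −0.84) with both trends removed. Over the same 5 settings the value nearest 0 was −0.98, a check that had as little room to come out otherwise. A change in total RNA content again stays untested. The ribosome biogenesis list was written, with its prediction, before its median was seen and without Srm, Hspd1 and Nup210, the genes that gave the idea; its median was at percentile 0 of its random lists. A candidate explanation is slower growth with treatment, but a culture nearer to confluence could also give both. Neither was tested, and no value here separates them.

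Several genes that were much higher in the PKCi library are known FOXO targets, which led to a list of others. Of its 26 measured genes 8 were at least 2-fold higher and 0 lower, with 20 above 0 and 6 below. The median was 0.57 (95% interval 0.23 to 1.00) at percentile 100. Mxi1 was taken out of this list after its first result, because its value had been seen in the hypoxia list; with it 9 of 27 were at least 2-fold higher and the list was at the 99.99 percentile. FOXO activity itself was not measured. The ubiquitin ligase gene Fbxo32 was at 3.60 and 18.7 CPM, Tsc22d3 at 11.0 and 46.9 CPM, and Irs2 at 26.8 and 82.3 CPM, chosen after their values were seen.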
